A study of Danio rerio with 30 samples.

How the data were processed

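Expression was measured by RNA sequencing in 30 libraries from the retina of zebrafish embryos (Danio rerio). The labels assign each library to the optic fissure region (OF) or to the dorsal retina (DR), which served as the control region, and to 32, 48 or 56 hours post-fertilisation (hpf). These times fall before, during and after fusion of the fissure. Each of the 6 groups held 5 biological replicates per the labels. Total RNA was isolated from dissected tissue with a kit made for fixed, paraffin-embedded material and amplified with a low-input kit, per the labels' protocols.

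The values are signal in the sense of normalised read counts: the deposited table gives, for 27731 genes, reads divided by a size factor of each library. Trim Galore, STAR 2.4.0, Picard, HTSeq, DESeq2 and the genome build GRCz10 are named in the submitters' processing notes, without role or order. The strand setting of the counting and the annotation release were not given in the sources used here. Low values in each column were whole multiples of 1 step, so that the reads behind them could be recovered, and 100.0% of values came out whole within 0.01 reads. In the DR library of replicate 3 at 48 hpf the step lay too near 1 for this check to tell reads from normalised counts. Size factors remove differences in total depth, so the values compare libraries on the assumption that most genes do not change. No reference genome was used here, and no coordinates are given. Gene symbols are those of the deposited table, and 24464 of its IDs also had an entry in a table of zebrafish gene names. Of the IDs, 24516 (88.4%) were protein-coding. Reads shared between close paralogs, which are many in zebrafish, could be split between genes in a way that the table does not show.

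Genes with a normalised count of at least 10 in at least 5 libraries were kept, which left 17360. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalised count + 1), with the 6 group means fitted to all 30 libraries and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The comparisons were OF against DR at each time, the difference of that contrast between times (interaction), and consecutive times within OF and within DR. All p-values are two-sided. The design had assumed normalised values of this kind, and no test had to be exchanged.

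Gene lists for retinal cell types, eye regions, signalling pathways, matrix and other cell types that a dissection could hold were fixed before the data were examined. There were 32 lists with 865 different genes. Of these, 816 were found by the name in the table, 21 by their current symbol and 11 by a synonym, while 17 were not found. Lists were tested with limma's camera, which asks whether the members moved relative to all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated correlation. A list was called at an adjusted p under 0.05 over the 32 lists. For a list, the number of called members is given over all genes and adjusted over the list alone.

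Named genes followed a rule: per comparison, the 8 largest increases and the 8 largest decreases among called genes with a symbol and a mean of at least 50 in the higher group, up to 4 members with the smallest adjusted p of each list described, and any member of the ventral, dorsal, netrin, basement membrane and coloboma lists. For calls at all 3 times the rule took 10 genes in each direction, and for the interaction the 8 with the smallest adjusted p. A group with 0 reads was set to a floor of 3 reads per library for a lower bound of the fold, which covers counting error only.

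Replicate numbers are shared between OF and DR. Deviations from the group means were correlated between libraries. For the 15 pairs with the same number and time, r ranged from 0.23 to 0.52 (median 0.38), and each of the 30 libraries correlated best with the one of its own number. Libraries of different numbers at one time had a median r of -0.1, and libraries of one number at different times a median of 0.04. The numbers therefore pair OF and DR within each time but not across times. A fit with the pair as a block is called the paired fit below. It left out the pairs of replicate 1 at 32 hpf and replicate 5 at 48 hpf, whose libraries stood apart, and kept 13 of the 15 pairs (4, 4 and 5 at 32, 48 and 56 hpf). DR replicate 1 at 56 hpf stood apart as well, with a read in 25740 genes against 18938 to 20240 in its group, but was kept. This fit was added after the data had been seen. The 48 hpf pair was doubted because of its ventral and dorsal genes, so the 48 hpf values of those genes without it are not independent evidence.

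Alternatives changed 1 choice at a time: pseudocount, filter, TMM or quantile scaling, blocks, robust or weighted fits, only the groups compared, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Values of edgeR and DESeq2 rest on those reads. The limma fits of the comparisons between regions, of consecutive times and of the interaction between 32 and 48 hpf, the paired fit, and edgeR and DESeq2 at 48 hpf were tested on simulated data, in which 200 of 17360 genes were changed. The other alternatives were not. Changed genes had a mean of at least 50, so the shares do not hold for lower genes. A pair effect was simulated for the paired fit alone, so its shares are not alike to the others. Apart from this the simulated libraries shared no structure, so calls of unchanged genes may be more in the real data. For OF against DR at 32 hpf, 25.4% of 2-fold, 86.6% of 4-fold and 95.5% of 8-fold changes were recovered. At 48 hpf the shares were 41.8%, 82.1% and 95.5%, and at 56 hpf 31.3%, 73.1% and 95.5%. The paired fit recovered 13.4%, 73.1% and 95.5% at 32 hpf, 22.4%, 73.1% and 95.5% at 48 hpf, and 31.3%, 73.1% and 97% at 56 hpf. Unchanged genes were called as well, 5, 3 and 5 at 32, 48 and 56 hpf with all libraries and 9, 11 and 4 in the paired fit. At 48 hpf edgeR recovered 40.3%, 83.6% and 98.5% and called 7 unchanged genes, and DESeq2 recovered 44.8%, 92.5% and 93.9% and called 28. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 16.6 in the 60 replicate pairs, so none was treated as a copy of another. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.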

Results

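Zebrafish retina was profiled in the region of the optic fissure, a gap in the ventral optic cup that fuses during development and leaves a coloboma when it stays open, and in the dorsal retina, which does not fuse. Libraries from OF and DR were sampled at 32 hpf (before fusion), 48 hpf (during fusion) and 56 hpf (after fusion), with 5 biological replicates each. No group held ventral retina away from the fissure. Differences between OF and DR therefore cannot tell the fissure from ventral position. Reads in genes ranged from 4.49 M to 12.32 M per library, with a median of 9.75 M. Between 11777 and 25740 genes had a read. Ribosomal protein genes took 10.62% ± 5.12 of reads in OF and 10.53% ± 5.56 in DR at 32 hpf (SD, n = 5), against 5.33% ± 0.80 and 6.69% ± 1.34 at 48 hpf and 5.16% ± 0.77 and 5.86% ± 1.05 at 56 hpf. The first principal component held 48.4% of the variance and the second 9.7%. At 32 hpf both libraries of replicate 1 stood apart, with 13854 (OF) and 11777 (DR) genes with a read and 18.94% and 20.1% of reads in ribosomal protein genes.

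Genes of ventral and dorsal eye identity were read in every library first, because they test the region labels. At 32 and 56 hpf every OF library had more vax2 and aldh1a3 and less tbx5a and aldh1a2 than every DR library. In the replicate 5 pair at 48 hpf these genes went against the labels. The library labelled OF held 18 normalised counts of vax1, 22 of vax2 and 0 of aldh1a3, where the other OF libraries of that time held 702 to 867, 377 to 550 and 255 to 752. The library labelled DR of the same pair held 768, 342 and 565 of these genes, where the other DR libraries held 1 to 6, 0 to 20 and 0 to 1. The dorsal genes bambia (1387 labelled OF, 433 labelled DR) and aldh1a2 (569 and 90) were also turned around. tbx5a was low in both libraries (14 and 1), where the other OF libraries held 0 to 15 and the other DR libraries 52 to 161. The labels were kept as given in all tests of all 30 libraries. For OF against DR, values without this pair are given beside them. Changes over time within a region are given with the pair in, except for some lists.

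**Figure D1:**
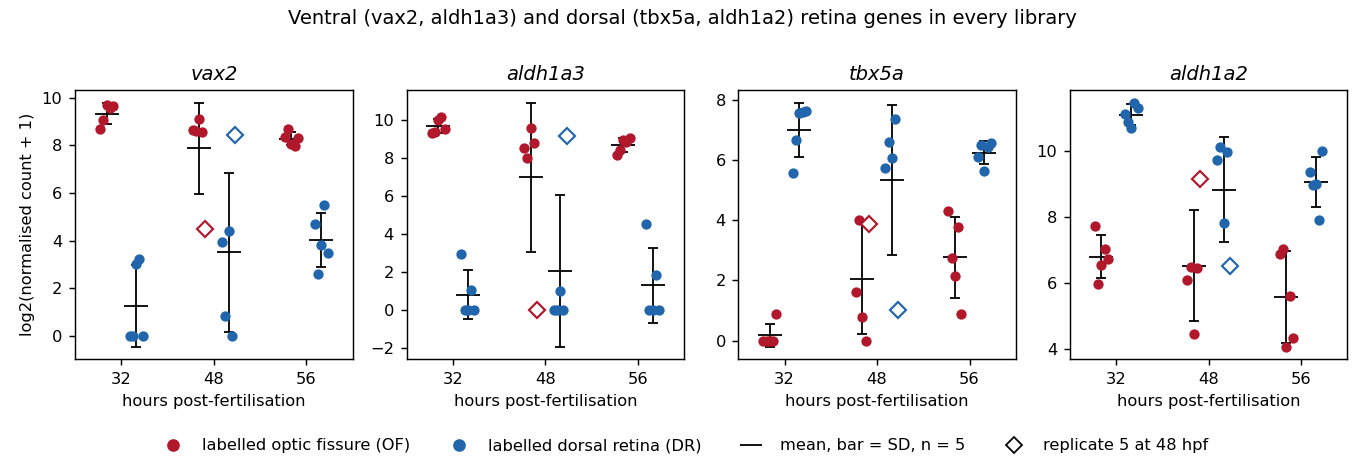
Normalised counts of the ventral genes vax2 and aldh1a3 and the dorsal genes tbx5a and aldh1a2, as log2(normalised count + 1), against hours post-fertilisation, with 1 point per library in red (labelled OF) or blue (labelled DR), black dashes for means and bars for the SD (n = 5). The open diamonds, replicate 5 at 48 hpf, lie with or near the other region for vax2 (22 counts labelled OF, 342 labelled DR), aldh1a3 and aldh1a2, while for tbx5a both lie low, at 14 and 1 counts.

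Before fusion, at 32 hpf, the optic fissure expressed genes of ventral eye identity that were close to absent from the dorsal retina. The homeobox gene vax1 (ENSDARG00000021916), needed in the ventral retina and optic stalk, had 832 ± 297 normalised counts in OF and 0.76 ± 1.7 in DR (SD, n = 5), a log2 fold change of 9.17 (SE 1.14, adjusted p = 1.2e-05). Its paralog vax2 (ENSDARG00000058702) had 666 ± 184 and 3.1 ± 4.27 (log2 fold change 8.08, SE 1.05, adjusted p = 2.3e-05). The retinoic acid synthesis gene aldh1a3 (ENSDARG00000076933) had 837 ± 229 in OF, while 3 reads in all were found in DR (adjusted p = 5.9e-04). Several genes of secreted factors were also higher in OF, although no list of secreted factors was tested. They included ntn1a, which encodes netrin-1 and is known from fissure fusion (1077 ± 244 against 38.8 ± 33.3, log2 fold change 5.08, SE 0.53, adjusted p = 1.3e-06). The BMP antagonist gene grem2b was another (647 ± 279 against 1.86 ± 2.58, log2 fold change 8.22, SE 0.97, adjusted p = 7.7e-06). The matrix genes smoc1 and smoc2 followed. smoc2 had 319 ± 115 in OF and 1.65 ± 2.37 in DR (log2 fold change 7.30, SE 0.99, adjusted p = 4.3e-05). smoc1 had no read in DR and was at least 25-fold higher in OF (adjusted p = 0.0194), as was the forkhead gene foxi2 by at least 104-fold (adjusted p = 0.0155). Both calls ended when single OF libraries were left out, smoc1 without replicate 2, 3 or 4 (adjusted p = 0.059, 0.067 and 0.057) and foxi2 without replicate 3 or 4 (0.056 and 0.054). OF replicate 1, whose pair the paired fit leaves out, had no read of either gene. In the other 4 of 4 pairs both were higher in that fit (adjusted p = 1.7e-06 for smoc1 and 2.2e-08 for foxi2). fam132a was higher too, at 536 ± 92.9 against 3.81 ± 3.52 (adjusted p = 1.4e-07).

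T-box and BMP-related genes of the dorsal eye were lower in OF at 32 hpf. tbx5b had 8.09 ± 9.8 normalised counts in OF and 292 ± 59.8 in DR (log2 fold change -5.69, SE 0.62, adjusted p = 2.0e-06), and tbx5a had 1 read over the 5 OF libraries against a mean of 145 ± 67.8 in DR (adjusted p = 2.3e-05). The T-box genes tbx3a (log2 fold change -3.24, SE 0.36), tbx4 (-3.19, SE 0.53) and tbx2a (-1.46, SE 0.23) were lower as well, with adjusted p of 2.0e-06, 8.4e-04 and 3.6e-04. The retinoic acid synthesis gene of the dorsal retina, aldh1a2, had 120 ± 55.5 in OF and 2238 ± 473 in DR (log2 fold change -4.30, SE 0.68, adjusted p = 4.5e-04). bambia, a BMP pseudoreceptor, had 351 ± 157 and 3865 ± 931 (log2 fold change -3.58, SE 0.43, adjusted p = 8.2e-06). The ligand gene bmp4 (-1.48, SE 0.25, adjusted p = 8.9e-04), the ephrin gene efnb2a (-2.80, SE 0.43, adjusted p = 2.5e-04), the netrin receptor gene unc5b (-3.62, SE 0.55, adjusted p = 2.3e-04) and the forkhead gene foxi1 (5.06 ± 8.48 against 112 ± 67.5, adjusted p = 0.00259) were lower in OF.

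Of 12 tested members of the ventral list, 8 were higher in OF over all genes and 10 when adjusted over the list alone (median log2 fold change 3.25, camera adjusted p = 1.2e-25, and 3.3e-04 with an estimated correlation). Of 12 dorsal members, 8 were lower and 12 when adjusted over the list alone (median -3.02, camera adjusted p = 1.4e-41, and 4.7e-06 with an estimated correlation). Of 29 orthologues of human coloboma genes, 6 were higher and 1 lower, and 13 and 2 when adjusted over the list alone. Among them were vax1, aldh1a3, ntn1a and the retinol receptor gene stra6 (985 ± 216 against 419 ± 83.2, log2 fold change 1.23, SE 0.25, adjusted p = 0.0077). This list had a camera adjusted p of 1.3e-05, and an adjusted p = 0.0319 with an estimated correlation. pax2a, a paired-box gene of the optic stalk, had 703 ± 212 in OF and 134 ± 69.7 in DR, and its difference passed the test only in the paired fit (adjusted p = 0.31 against 0.0459). In the netrin and axon guidance list 3 of 25 members were higher and 1 lower, and 5 and 1 when adjusted over the list alone (camera adjusted p = 2.2e-04, adjusted p = 0.0506 with an estimated correlation). Besides ntn1a and unc5b these were nrp1a, a semaphorin receptor gene (log2 fold change 1.38, SE 0.25, adjusted p = 0.00199), and sema3fb, which had no read in DR and was at least 4-fold higher (adjusted p = 6.1e-04). Of 36 BMP and TGF-beta genes 4 were higher and 4 lower, and 5 and 10 when adjusted over the list alone (median -0.28, camera adjusted p = 0.00419, adjusted p = 0.336 with an estimated correlation, and 0.00684 in the paired fit). smad6a, an inhibitory Smad gene, was lower (-1.41, SE 0.24) and the receptor gene tgfbr2b, chosen after its values were seen, higher (3.99, SE 0.77). The ephrin receptor gene ephb2b was also higher (2.16, SE 0.34). The basement membrane list of 23 genes was called with all libraries (median 0.72, or 0.46 at the bound, camera adjusted p = 0.00925, adjusted p = 0.394 with an estimated correlation). Of its members 2 were higher when adjusted over the list alone and none over all genes. Its call ended with a mean filter of 50 (adjusted p = 0.097) and without OF replicate 1 (0.1) or DR replicate 3 (0.084). Of these genes, 2 were higher and 1 lower in the paired fit, and 5 and 1 when adjusted over the list alone (camera adjusted p = 0.00475, adjusted p = 0.266 with an estimated correlation).

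Other cell types differed between the regions at 32 hpf. Of 26 genes of endothelium and hyaloid vessels 4 were higher in OF, and 20 when adjusted over the list alone (median 2.14, camera adjusted p = 6.0e-18, and 0.0116 with an estimated correlation). The endothelial ETS factor gene erg had 38.3 ± 33.9 normalised counts in OF and 1 read over the 5 DR libraries (adjusted p = 9.5e-04, and 0.056 after quantile scaling). Its relative etv2 was higher in the paired fit (2.35, SE 0.37, adjusted p = 8.0e-04), as was the vascular cadherin gene cdh5 (1.53, SE 0.37, adjusted p = 0.0277). Of 24 erythrocyte genes 3 were higher, and 14 when adjusted over the list alone (median 3.03, camera adjusted p = 2.2e-14, and 0.0424 with an estimated correlation). The erythrocyte list had an adjusted p = 0.085 with an estimated correlation in the paired fit. The red cell carbonic anhydrase gene cahz had 137 ± 79.6 in OF and 20.03 ± 28.4 in DR (log2 fold change 4.15, SE 0.83, adjusted p = 0.00611), and the anion exchanger gene slc4a1a was higher in the paired fit (5.12, SE 0.83, adjusted p = 0.001). Globin genes took 0.165% ± 0.218 of reads in OF and 0.050% ± 0.090 in DR (SD, n = 5), and the share was higher in OF in 5 of 5 pairs. Both means rest on replicate 1, at 0.551% in OF and 0.21% in DR, while the other libraries had at most 0.12% and 0.025%. Of 26 genes of periocular mesenchyme and neural crest 1 was higher, and 4 when adjusted over the list alone (median 0.73, camera adjusted p = 0.00925, adjusted p = 0.67 with an estimated correlation). The call of this list ended with a mean filter of 50 (adjusted p = 0.097) and without OF replicate 4 (0.17) or 5 (0.052). Its paired-fit median was 1.01, with 4 higher and 7 when adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.0928 with an estimated correlation). Of 21 fibrillar collagen and matrix genes 4 were higher in that fit, and 9 when adjusted over the list alone (median 1.04, camera adjusted p = 2.9e-05, adjusted p = 0.165 with an estimated correlation). With all libraries this list was not called (median 0.44, camera adjusted p = 0.1). Of 26 retinal ganglion cell genes 3 were higher, and 7 when adjusted over the list alone (median 1.02, camera adjusted p = 2.4e-07, adjusted p = 0.336 with an estimated correlation). The T-box gene eomesa had 165 ± 119 in OF and 3.13 ± 4.75 in DR (log2 fold change 5.46, SE 0.73, adjusted p = 4.3e-05). The neuronal RNA-binding gene elavl4 (1.97, SE 0.27, adjusted p = 2.0e-04) and the adhesion gene alcama (1.23, SE 0.22, adjusted p = 0.00221) were higher in the paired fit.

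At 32 hpf, 198 of 17360 genes differed between OF and DR, 169 higher and 29 lower in OF (85.4% higher), and 13 of the 32 lists were called, 5 of them with an estimated correlation. With every pair blocked 489 genes differed, and in the paired fit 565 (487 higher, 78 lower), which kept 175 of the 198 calls with their direction. Quantile scaling left 99 genes (72.7% higher). A fit to the 32 hpf libraries alone left 39. It ended the calls of smoc1 and foxi2 (adjusted p = 0.31 and 0.3) of tbx2a, foxi1, bmp4 and smad6a (0.24, 0.11, 0.16 and 0.26), and of cahz, eomesa and tgfbr2b (0.73, 0.12 and 0.35). With edgeR, foxi1, cahz and tgfbr2b missed the threshold (0.064, 0.057 and 0.15). Genes given from the paired fit alone either missed the threshold without the block or lost their call when single libraries were left out.

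During fusion, at 48 hpf, 1 gene differed with all 30 libraries, saga, which encodes the rod arrestin: 318 ± 348 normalised counts in OF and 4.05 ± 5.91 in DR (SD, n = 5; log2 fold change 5.46, SE 0.93, adjusted p = 0.0387). Its call ended without OF replicate 1, 2 or 3 (adjusted p = 0.23, 0.29 and 0.34) or DR replicate 1, 3 or 4 (0.12, 0.078 and 0.14). It also ended with a pseudocount of 0.5 (0.067), without the filter (0.068), with a filter at a mean of 50 (0.057) and with the 48 hpf libraries alone (0.65). With single libraries left out the number of genes was 0 without any of those 6 libraries, 2 without OF replicate 4, 23 without DR replicate 5 and 52 without OF replicate 5. The unadjusted p was under 0.05 for 687 genes, and edgeR called 3 genes and DESeq2 25. On simulated data of this comparison DESeq2 called 28 unchanged genes, and limma 3. With every pair blocked 35 genes differed.

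In the paired fit, without the replicate 5 pair, 781 genes differed at 48 hpf (527 higher and 254 lower in OF), with the same direction in 4 of 4 pairs for each gene named here. Photoreceptor genes were among those higher in OF. Rod opsin, rho, had 9120 ± 9625 normalised counts in OF and 47.3 ± 93.9 in DR (SD, n = 4; log2 fold change 10.15, SE 1.09, adjusted p = 2.2e-05), and 0.15 with all libraries and no block. In the replicate 5 pair, left out here, rho had 1.60 normalised counts in OF and 8.18 in DR. The mean of the photoreceptor list differed by 0.05 within that pair, so leaving it out favours these genes. The cone arrestin gene arr3a (7.30, SE 0.67, adjusted p = 4.3e-06), the ultraviolet cone opsin gene opn1sw1 (7.18, SE 0.85, adjusted p = 7.8e-05), the rod transducin gene gngt1 (6.37, SE 0.62, adjusted p = 7.8e-06) and saga (6.47, SE 0.63, adjusted p = 7.8e-06) were higher. Of 50 photoreceptor genes 22 were higher, and 39 when adjusted over the list alone (median 2.05, camera adjusted p = 1.1e-25, and 0.00209 with an estimated correlation). With all libraries and no block the list was also called (median 1.65, camera adjusted p = 7.7e-28, adjusted p = 0.05 with an estimated correlation). Among regional genes, vax1 had 783 ± 72.0 in OF and 3.22 ± 2.63 in DR (7.78, SE 0.59, adjusted p = 3.0e-07), and vax2 (6.44, SE 0.67), pax2a (4.97, SE 0.69), grem2b (5.40, SE 0.60) and ephb2b (1.79, SE 0.16) were higher. aldh1a3 had 453 ± 213 in OF and 1 read in all in DR. tbx4 (-3.60, SE 0.33), aldh1a2 (-3.55, SE 0.43), tbx5a (-4.83, SE 0.67), bambia (-2.93, SE 0.15), efnb2a (-2.72, SE 0.19), foxi1 (-5.71, SE 0.68) and the BMP-family ligand gene gdf6a (-4.10, SE 0.78) were lower, with adjusted p between 1.6e-09 and 0.00624. Of these regional genes, vax1, vax2, aldh1a3 and bambia had adjusted p of 0.113, 0.156, 0.534 and 0.107 with all libraries and no block.

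The ventral list had 10 of 12 members higher at 48 hpf in the paired fit and 10 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.5e-15, and 0.00306 with an estimated correlation), and the dorsal list 6 lower by either count (camera adjusted p = 1.8e-12, and 0.00306 with an estimated correlation). These lists are not independent evidence here, since the pair was left out for the same genes. With all libraries both were also called (camera adjusted p = 2.3e-12 and 3.7e-10, and 0.0283 each with an estimated correlation). Of 29 coloboma genes 10 were higher and 1 lower in the paired fit, and 11 and 1 when adjusted over the list alone (camera adjusted p = 2.6e-05, and 0.0256 with an estimated correlation). The same limit holds here, as vax1 and aldh1a3 are in this list. With all libraries 7 were higher and 1 lower when adjusted over the list alone and none over all genes (camera adjusted p = 7.8e-05, adjusted p = 0.0555 with an estimated correlation). Cell cycle genes were lower as a group in the paired fit (median -0.32, camera adjusted p = 4.0e-13, adjusted p = 0.0956 with an estimated correlation), 6 of 32 members over all genes and 11 when adjusted over the list alone. With all libraries the median was -0.26 (camera adjusted p = 6.9e-09, adjusted p = 0.284 with an estimated correlation), and no member passed over all genes or when adjusted over the list alone. The replication clamp gene pcna had 11070 ± 4101 in OF and 19640 ± 6875 in DR (paired fit, SD, n = 4; log2 fold change -0.83, SE 0.13, adjusted p = 0.00102). Lists of other tissues were called too. Of 32 muscle genes 2 were higher in OF in the paired fit, and 7 when adjusted over the list alone (median 1.31, camera adjusted p = 2.3e-04, adjusted p = 0.482 with an estimated correlation). With all libraries the muscle median was 1.11 (camera adjusted p = 0.00353, adjusted p = 0.696 with an estimated correlation). This call ended with library weights (adjusted p = 0.24) and without OF replicate 2, 4 or 5 (0.13, 0.16 and 0.17) or DR replicate 1 (0.082). The erythrocyte list was lower with all libraries (median -0.69, camera adjusted p = 0.00338, adjusted p = 0.603 with an estimated correlation). Its call ended without DR replicate 1 (adjusted p = 0.098), without the replicate 5 pair (0.054) and in the paired fit (0.0543). Genes of retinal pigment epithelium and pigment cells were higher as a list with all libraries (median 0.36, camera adjusted p = 1.6e-04, adjusted p = 0.136 with an estimated correlation). Of 26 such genes 2 were higher when adjusted over the list alone and none over all genes. In the paired fit 3 were higher, and 8 when adjusted over the list alone, but the list was not called (median 0.25, camera adjusted p = 0.0543).

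After fusion, at 56 hpf, photoreceptor genes were higher in OF. rho (ENSDARG00000002193) had 17320 ± 9799 normalised counts in OF and 153 ± 211 in DR (SD, n = 5; log2 fold change 10.44, SE 1.83, adjusted p = 0.00377), and the cone arrestin gene arr3b had 687 ± 291 and 4.85 ± 9.74 (8.07, SE 1.04, adjusted p = 2.5e-04). The cone transducin gene gnb3b (6.30, SE 1.09, adjusted p = 0.00372), gngt1 (5.77, SE 1.05, adjusted p = 0.00556), the outer segment gene rom1a (5.63, SE 0.97, adjusted p = 0.00372), the recoverin gene rcvrn3 (5.39, SE 0.94, adjusted p = 0.00377) and the retinoid-binding gene rbp2a (5.84, SE 1.03, adjusted p = 0.00385) were higher, each in 5 of 5 pairs. Of 50 photoreceptor genes 9 were higher, and 27 when adjusted over the list alone (median 2.78, camera adjusted p = 6.2e-40, and 0.0108 with an estimated correlation). With pairs blocked in the paired fit 31 were higher, and 44 when adjusted over the list alone, opn1sw1 among them (7.54, SE 0.76, adjusted p = 1.1e-05). Without the block the calls of rho, gnb3b, rom1a and rcvrn3 ended with edgeR (adjusted p = 0.16, 0.057, 0.18 and 0.48) and with DESeq2 (0.12, 0.065, 0.33 and 0.56). Lists of non-retinal tissue were called higher in OF as well. The muscle list had a median of 0.87 (camera adjusted p = 0.0384, adjusted p = 0.738 with an estimated correlation, and camera adjusted p = 0.00736 in the paired fit). The erythrocyte list had a median of 1.05 (camera adjusted p = 0.0274, adjusted p = 0.662 with an estimated correlation, and camera adjusted p = 0.0316 in the paired fit). No member of either passed in these fits, over all genes or when adjusted over the list alone. Single libraries decided both calls. The muscle median was -0.01 without OF replicate 1, and the call ended without it (adjusted p = 0.67), OF replicate 2 (0.96) or DR replicate 3, 4 or 5 (0.24, 0.53 and 0.48). It also ended without both replicate 1 libraries at 32 hpf (0.074), with both doubted pairs left out (0.074) and with the 56 hpf libraries alone (0.25). The erythrocyte call ended without OF replicate 1 or 3 (0.12 and 0.078) or DR replicate 4 (0.83), and with the 56 hpf libraries alone (0.051).

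**Figure D2:**
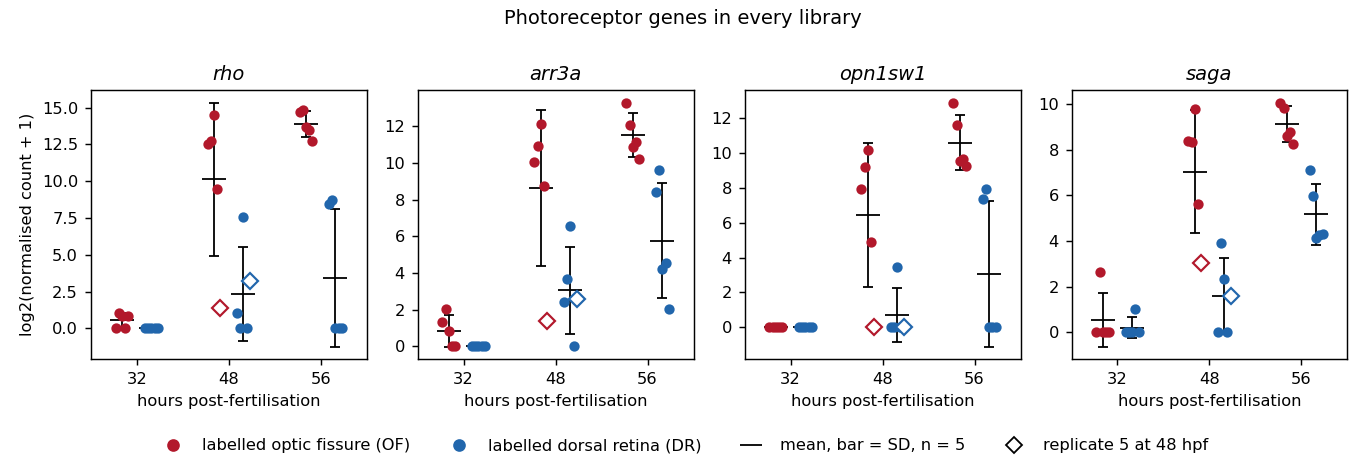
Normalised counts of the photoreceptor genes rho, arr3a, opn1sw1 and saga, as log2(normalised count + 1), against hours post-fertilisation, with 1 point per library in red (labelled OF) or blue (labelled DR), black dashes for means and bars for the SD (n = 5). At 56 hpf the mean of rho was 17320 in OF and 153 in DR, and at 48 hpf both open diamonds of replicate 5 lie low, at 2 and 8 counts of rho.

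Some regional genes differed at 56 hpf as well. vax1 had 649 ± 103 normalised counts in OF and 10.01 ± 8.66 in DR (SD, n = 5; log2 fold change 6.47, SE 1.14, adjusted p = 0.00385, and 0.057 with edgeR). tbx4 had 20.01 ± 8.97 and 259 ± 47.8 (-3.78, SE 0.53, adjusted p = 3.6e-04), bambia 248 ± 50.7 and 1639 ± 304 (-2.73, SE 0.43, adjusted p = 0.00153), and efnb2a 257 ± 53.7 and 1407 ± 205 (-2.46, SE 0.43, adjusted p = 0.00372). In the paired fit, aldh1a3 (7.40, SE 0.57), grem2b (4.92, SE 0.54), smoc1 (4.86, SE 0.57), pax2a (4.54, SE 0.62), ntn1a (2.61, SE 0.34), ephb2b (1.62, SE 0.14) and stra6 (0.99, SE 0.23) were higher, with adjusted p between 5.0e-07 and 0.0159. foxi1 (-4.52, SE 0.61), aldh1a2 (-3.48, SE 0.38), tbx5b (-2.83, SE 0.43) and the orphan receptor genes nr2f2 (-1.61, SE 0.15) and nr2f1a (-1.43, SE 0.23) were lower. Of 12 ventral genes 5 were higher, and 9 when adjusted over the list alone (median 2.74, camera adjusted p = 6.3e-18, and 0.00331 with an estimated correlation). Of 12 dorsal genes 4 were lower, and 6 when adjusted over the list alone, against 8 and 12 at 32 hpf (median -1.70, camera adjusted p = 7.2e-18, and 0.00287 with an estimated correlation). The list was not tested for a change between 32 and 56 hpf. The coloboma list had 5 of 29 members higher, and 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.0e-05, and 0.0347 with an estimated correlation). Of 25 netrin and axon guidance genes 2 were higher, by all genes and adjusted over the list alone (camera adjusted p = 0.00727, adjusted p = 0.195 with an estimated correlation). The netrin receptor gene unc5c (3.18, SE 0.62, adjusted p = 0.00548) and the adhesion gene tenm3 (1.45, SE 0.18, adjusted p = 1.3e-04) were higher in the paired fit.

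Cell cycle genes were lower in OF at 56 hpf as a group (median -0.51, camera adjusted p = 2.1e-22, adjusted p = 0.0612 with an estimated correlation). Of 32 members 23 were lower in the paired fit, and 28 when adjusted over the list alone (camera adjusted p = 8.3e-31, and 0.0128 with an estimated correlation). pcna had 8307 ± 2410 normalised counts in OF and 14860 ± 3157 in DR (SD, n = 5; log2 fold change -0.87, SE 0.11, adjusted p = 2.0e-04 in the paired fit and 0.2 without the block). The replication licensing genes mcm3 (-0.85, SE 0.14) and cdc6 (-0.92, SE 0.16) were lower in the paired fit. Of 33 progenitor genes 2 were higher and 11 lower in that fit, and 5 and 14 when adjusted over the list alone (camera adjusted p = 5.8e-05, and 0.0192 with an estimated correlation). notch1b (-0.82, SE 0.15) and the cyclin gene ccnd1 (-0.68, SE 0.11) were lower, and the homeobox gene six6a was higher (2.25, SE 0.33, adjusted p = 5.0e-04). Of 13 bipolar cell genes 5 were higher, and 7 when adjusted over the list alone (median 0.73, camera adjusted p = 8.0e-07, and 0.0128 with an estimated correlation), with the G protein gene gnao1b (1.43, SE 0.18) and the calcium-binding gene cabp5a (3.04, SE 0.58) among them. Without the block the progenitor and bipolar lists had an adjusted p = 0.141 and 0.331 with an estimated correlation.

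At 56 hpf, 44 genes differed between OF and DR, 35 higher and 9 lower in OF (79.5% higher), and 13 lists were called, 4 of them with an estimated correlation. With every pair blocked 390 genes differed, and in the paired fit 820 (418 higher, 402 lower), which kept 44 of the 44. Both fits hold the same 56 hpf libraries. The pairs left out at the other times enter through the shared estimate of the spread. Without the block the number was 26, 25 and 25 without OF replicate 1, 2 and 4, and 25, 21 and 22 without DR replicate 3, 4 and 5. edgeR called 8 genes with all libraries and no block, and 912 in the design of the paired fit, where the block and the libraries both change. As at 32 hpf, genes given from the paired fit alone missed the threshold without the block or lost their call without single libraries.

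**Figure D3:**
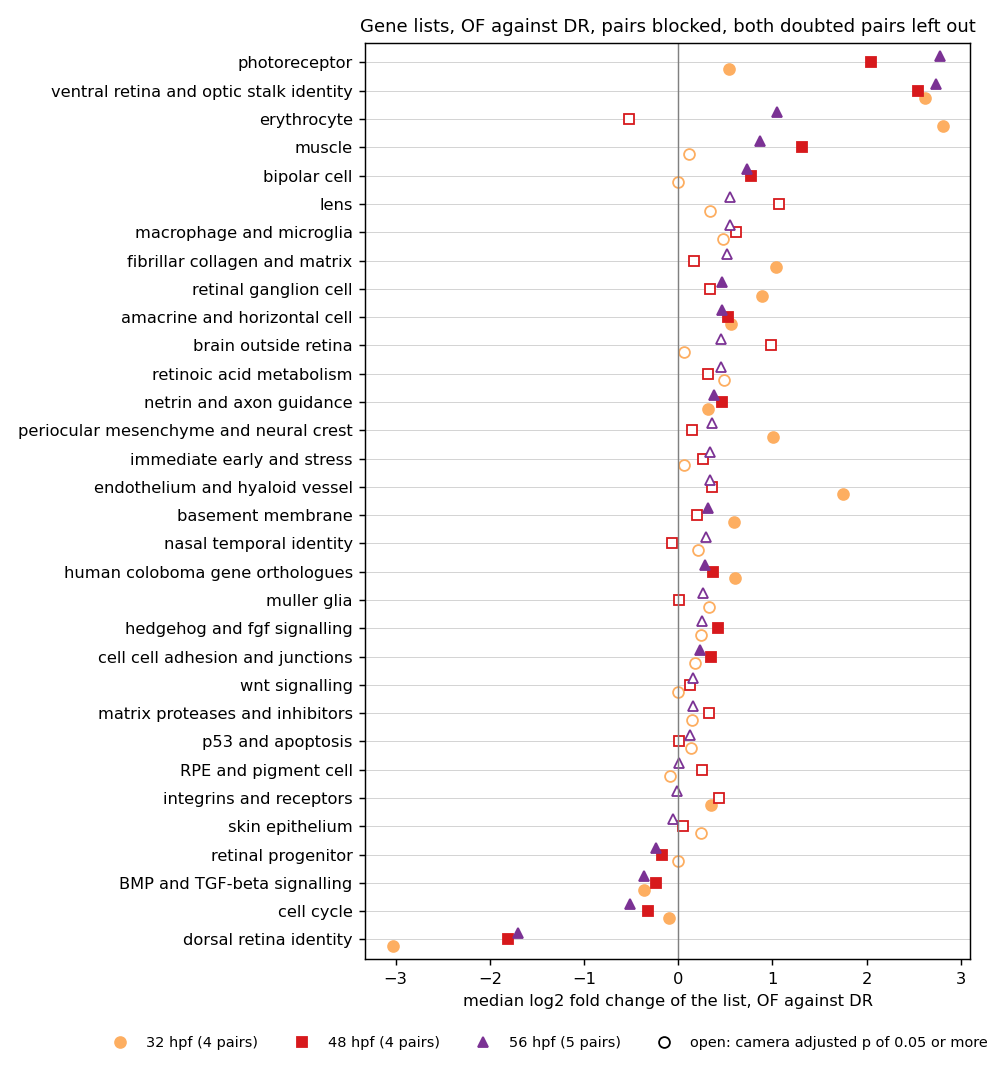
Median log2 fold change of each of the 32 gene lists, OF against DR, in the paired fit at 32 hpf (circles, 4 pairs), 48 hpf (squares, 4 pairs) and 56 hpf (triangles, 5 pairs). Filled symbols have a camera adjusted p under 0.05; the photoreceptor median was 2.05 at 48 hpf and 2.78 at 56 hpf, and the dorsal median was -3.03 at 32 hpf.

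Calls shared by the times were counted next. With all libraries and limma, 0 genes differed in 1 direction at all 3 times (68 at an unadjusted p under 0.05, 0 with edgeR and 4 with DESeq2), since 48 hpf had a single call. Without the OF or the DR library of replicate 5 at 48 hpf the number was 12 or 17. Between 32 and 56 hpf, 8 genes were higher and 8 lower in OF at both times, where independent lists would share 0.341 and 0.015. In the paired fit 87 genes differed in 1 direction at all 3 times, 66 higher and 21 lower, where independent lists would share 0.36 and 0.026, and with every pair blocked 1 did. The 10 genes with the largest mean fold were aldh1a3, vax1, foxi2, vax2, smoc2, grem2b, smoc1, bmpr1bb (ENSDARG00000102742, whose symbol another gene shares), fam132a and the claudin gene cldn11a on the higher side. On the lower side they were tbx5a, foxi1, gdf6a, aldh1a2, tbx5b, tbx4, bambia, efnb2a, nr2f2 and a gene named only by its clone.

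Whether the difference between regions changed with time was tested as an interaction. On simulated data of 32 to 48 hpf the fit to all libraries recovered 3% of 2-fold, 53.7% of 4-fold and 80.3% of 8-fold changes. The paired fit recovered 3%, 32.8% and 74.2%. Unchanged genes were called as well, 1 and 3. The interaction between 48 and 56 hpf was not simulated. Few calls therefore do not show that the difference stayed alike. Between 32 and 48 hpf the difference between regions changed in 1 gene with all libraries, tbx3a (difference of log2 fold changes 3.49, SE 0.50, adjusted p = 0.00206). Its log2 fold change in the paired fit was -3.09 at 32 hpf, 0.22 at 48 hpf and 0.06 at 56 hpf. That fit called 70 genes, 48 with a gain in OF relative to DR and 22 with a loss, while 2 were called with every pair blocked. Photoreceptor genes gained, with gngt1 (6.36, SE 0.88, adjusted p = 0.00312), arr3a (6.58, SE 0.94, adjusted p = 0.00388) and saga (6.06, SE 0.88, adjusted p = 0.0043) among them. Of the 70, 12 belonged to the 50 photoreceptor genes, where 0.2 were expected by chance (exact hypergeometric p = 7.4e-19 across genes, which are not independent). This share is not independent evidence either. In the 48 hpf pair left out, the mean of the photoreceptor list differed by 0.05, against 2.22 to 3.16 in the other pairs of that time. Leaving it out therefore favours these genes. ntn1a lost most of its gap, from a log2 fold change of 5.56 at 32 hpf to 1.65 at 48 hpf (difference -3.91, SE 0.54, adjusted p = 0.00312), and missed the threshold with all libraries (adjusted p = 0.0946). Between 48 and 56 hpf limma called 0 genes (90 at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2), and 0 in the paired fit (547 unadjusted). The test over any time called tbx3a with all libraries (adjusted p = 0.00121). It called 2 genes without OF replicate 5 at 32 hpf, 4 without DR replicate 1 or replicate 3 at 32 hpf, 7 without OF replicate 5 at 48 hpf and 3 without DR replicate 5 at 48 hpf. For 48 against 32 hpf the number was 2, 3, 4 and 2 without OF replicate 5, DR replicate 1 or DR replicate 3 at 32 hpf, or DR replicate 5 at 48 hpf.

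From 32 to 48 hpf neuronal differentiation genes rose in OF. calb2b, the calretinin gene of amacrine cells, rose from 2.75 ± 2.67 to 2901 ± 2459 normalised counts (SD, n = 5; log2 fold change 9.26, SE 0.78, adjusted p = 4.7e-10), and the transducin gene gnb3a from 9.36 ± 11.4 to 5454 ± 4165 (9.11, SE 0.85, adjusted p = 3.3e-09). The mitochondrial creatine kinase gene ckmt2a (8.51, SE 0.67, adjusted p = 1.3e-10) and the forkhead gene foxq2 (8.49, SE 0.41, adjusted p = 7.3e-15) rose too. rho went from 3 reads in all to a mean of 7297 ± 9279 (adjusted p = 1.4e-04). Of 26 retinal ganglion cell genes 24 rose and 1 fell, the same when adjusted over the list alone (median 3.55), with isl2a (7.16, SE 0.64) as an example and pou4f3 going from 0 reads to a mean of 239.5 ± 103. Of 24 amacrine and horizontal cell genes 21 rose and 2 fell, likewise when adjusted over the list alone (median 4.32). They included the GABA synthesis gene gad2 (6.33, SE 0.52) and tfap2b (4.46, SE 0.47). Of 13 bipolar cell genes 10 rose, and 11 when adjusted over the list alone (median 3.27), with vsx1 (3.57, SE 0.30) and bhlhe23 (7.51, SE 0.74). Of 50 photoreceptor genes 41 rose, and 44 when adjusted over the list alone (median 4.25). They included neurod1 (2.47, SE 0.26) and prom1b, which went from 1 read in all to a mean of 422 ± 297. Cell cycle genes fell in 20 of 32 cases, and 21 when adjusted over the list alone (median -0.76). pcna went from 42540 ± 5846 to 12840 ± 5312 (log2 fold change -1.81, SE 0.24, adjusted p = 1.1e-06) and mcm6 (-1.78, SE 0.27). Of 33 progenitor genes 18 fell and 5 rose, and 22 and 5 when adjusted over the list alone (median -0.91), with rx1 (-1.54, SE 0.22) falling. Wnt pathway genes fell in 7 of 27 cases and rose in 2, the same when adjusted over the list alone (median -0.41). Among those that fell were tcf7l2 (-1.92, SE 0.27), tcf7l1a (-1.48, SE 0.21) and the secreted antagonist sfrp5 (-3.99, SE 0.61, adjusted p = 7.2e-06). The pyrimidine synthesis gene cad fell as well (-2.53, SE 0.30, adjusted p = 1.4e-07). Camera adjusted p were at most 4.2e-06 for the cell type and cell cycle lists and 0.00484 for the Wnt list. With an estimated correlation the progenitor list kept an adjusted p = 0.0344, its amacrine counterpart had an adjusted p = 0.182 and the others an adjusted p = 0.213. Lists of other tissues also had medians above 0 in OF, with genes of a group at 0 set to their bound. These were 2.49 for brain outside the retina, 3.13 for muscle and 0.78 for retinal pigment epithelium and pigment cells. Endothelial and erythrocyte genes went the other way (-0.04 and -0.66).

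In the dorsal retina neuronal genes also rose between 32 and 48 hpf. Differences between the regions in these changes were tested by the interaction above, gene by gene. calb2b had no read at 32 hpf and was at least 399-fold higher at 48 hpf (1712 ± 1611, adjusted p = 1.6e-10). gnb3a rose from 1.48 ± 2.05 to 2035 ± 1690 (log2 fold change 9.24, SE 0.85, adjusted p = 1.9e-09), the recoverin gene rcvrn2 from 3.45 ± 6.71 to 1317 ± 739 (9.01, SE 0.94, adjusted p = 1.7e-08) and the iroquois gene irx4a from 1.64 ± 3.66 to 536 ± 181 (8.32, SE 0.75, adjusted p = 1.4e-09). Of 26 ganglion cell genes 23 rose, and 24 when adjusted over the list alone (median 4.90, or 4.79 with genes of a group at 0 set to their bound). isl2a rose by 7.92 (SE 0.64), and pou4f3 went from 1 read in all to a mean of 139 ± 58.9. Of 24 amacrine and horizontal cell genes 20 rose and 2 fell by either count (median 4.70, or 4.56 at the bound). tfap2b rose by 5.04 (SE 0.47), and gad2 went from 2 reads in all to a mean of 237 ± 59.8. Of 13 bipolar genes 8 rose by either count (median 2.23), vsx1 by 3.51 (SE 0.30) and bhlhe23 by 8.18 (SE 0.74). Of 50 photoreceptor genes 21 rose and 1 fell, and 23 and 1 when adjusted over the list alone (median 1.94, or 1.53 at the bound). prdm1a rose by 6.59 (SE 0.64), and prom1b went from 0 reads to a mean of 206 ± 179. pcna fell by 1.32 on the log2 scale (SE 0.24, adjusted p = 1.1e-04) and mcm6 fell by 1.59 (SE 0.27). Of 32 cell cycle genes 14 fell, and 15 when adjusted over the list alone (median -0.59). Progenitor genes fell in 18 of 33 cases and rose in 6, and in 18 and 8 when adjusted over the list alone (median -0.55). rx1 (-1.41, SE 0.22) was among those that fell. The call of this list ended after quantile scaling (adjusted p = 0.3). In the Wnt list 7 of 27 fell and 1 rose by either count (median -0.46), with tcf7l2 (-1.71, SE 0.27), tcf7l1a (-1.24, SE 0.21), sfrp5 (-4.03, SE 0.61, adjusted p = 6.8e-06) and wnt8b (-3.94, SE 0.80, adjusted p = 3.4e-04). Camera adjusted p for these lists ran from 4.5e-19 (ganglion cells) to 1.8e-04 (Wnt). With an estimated correlation none of the DR lists was called. The ganglion cell and amacrine lists had an adjusted p = 0.0969, against an adjusted p = 0.107, 0.115, 0.231 and 0.52 for the progenitor, Wnt, cell cycle and photoreceptor lists, and 0.231 for the bipolar list. Genes of other cell types rose in DR as well. Of 26 endothelial genes 13 rose, and 15 when adjusted over the list alone (median 1.61, camera adjusted p = 0.0213). Of 24 erythrocyte genes 12 rose, and 13 when adjusted over the list alone (median 2.61, camera adjusted p = 0.0102). Of 26 periocular mesenchyme and neural crest genes 13 rose, and 18 when adjusted over the list alone (median 2.2, camera adjusted p = 0.0015). Of 21 macrophage and microglia genes 10 rose, and 11 when adjusted over the list alone (median 1.99, camera adjusted p = 0.0236). Each of these 4 lists had an adjusted p = 0.568 with an estimated correlation. In OF none of them was called. The medians there were -0.04 for endothelium, where the mean was 0.01, -0.66 for erythrocytes, 1.87 for mesenchyme and 1.97 for macrophages (camera adjusted p = 0.305, 0.0598, 0.0755 and 0.123). The erythrocyte list was called in OF with a pseudocount of 5 (adjusted p = 0.045), with the compared groups alone (0.0099), and without replicate 3 or 4 at 32 hpf (0.048 and 0.028) or replicate 3 at 48 hpf (0.036). The difference between the regions was not tested by list. The list of brain outside the retina, 11 genes, had a median of 2.89 in DR and 2.49 in OF at the bound. Globin genes took 0.050% of reads in DR at 32 hpf, with 0.21% in replicate 1 and at most 0.025% in the others, and 0.140% at 48 hpf. The endothelial call ended with quantile normalization (adjusted p = 0.11), with library weights (0.056), without DR replicate 1 at 32 hpf (0.052), without both replicate 1 libraries at 32 hpf (0.056), and with both doubted pairs left out (0.088). The erythrocyte call ended without DR replicate 5 at 32 hpf (0.071). The macrophage call ended with quantile normalization (0.19), with both doubted pairs left out (0.069), and without DR replicate 1 or 4 at 32 hpf (0.071 and 0.054) or replicate 2 at 48 hpf (0.075).

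**Figure D4:**
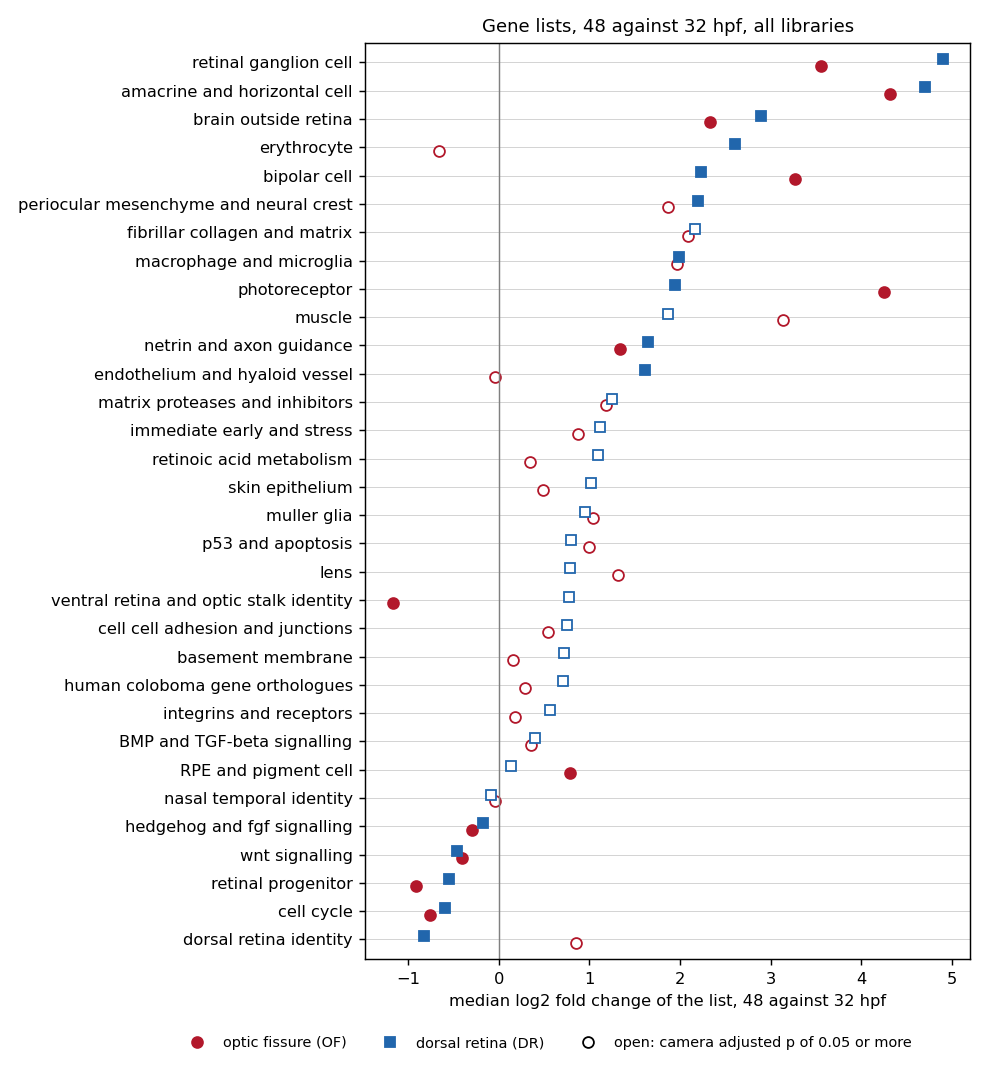
Median log2 fold change of each of the 32 gene lists from 32 to 48 hpf in OF (red circles) and DR (blue squares), all libraries, with filled symbols for a camera adjusted p under 0.05. Lists of retinal neurons lie to the right, at 3.55 in OF and 4.90 in DR for ganglion cells, and cell cycle genes to the left, at -0.76 and -0.59.

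In OF 6105 genes changed from 32 to 48 hpf, 4437 up and 1668 down (72.7% up), and in DR 4940, 3830 up and 1110 down (77.5% up). The median gene rose by 0.381 and 0.350 on the log2 scale. Quantile scaling lowered these medians, to -0.162 and -0.167, and put the shares of rising genes at 47.2% and 54.2%, so rises and falls are relative to the submitters' scaling. Each gene named kept its direction after quantile scaling. Library measures differed between these times too. Ribosomal protein genes took 10.62% of reads in OF and 10.53% in DR at 32 hpf, and 5.33% and 6.69% at 48 hpf. At a common depth of 4 M reads, 13371 to 17982 genes had a read in OF at 32 hpf and 18829 to 19499 at 48 hpf. In DR the ranges were 11722 to 17103 and 17850 to 18972. How far the counts of changed genes follow such differences was not tested.

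From 48 to 56 hpf few genes passed the threshold, and those that did belong to the daily clock. On simulated data 35.8% of 2-fold changes were recovered in OF and 26.9% in DR, so other genes may have changed as well. In OF the clock repressor gene per1b fell from 946 ± 193 to 138 ± 72.3 normalised counts (SD, n = 5; log2 fold change -2.90, SE 0.35, adjusted p = 5.4e-05) and per3 from 464 ± 70.0 to 183 ± 32.5 (-1.35, SE 0.22, adjusted p = 0.00418), while the cryptochrome gene cry1bb rose from 215 ± 50.7 to 567 ± 82.3 (1.42, SE 0.22, adjusted p = 0.00373). These 3 were all the calls in OF (665 genes at an unadjusted p under 0.05). In DR the 2 calls were per1b, from 852 ± 265 to 155 ± 48.7 (-2.45, SE 0.35, adjusted p = 0.00154), and cry1bb, from 194 ± 18.7 to 478 ± 126 (1.26, SE 0.22, adjusted p = 0.0296). cry1bb lost its call in DR in 9 of the 10 leave-one-out fits, all but the one without DR replicate 1 at 56 hpf (adjusted p from 0.065 to 0.24), and with TMM scaling (0.067), the number as a block (0.063) or the DR libraries alone (0.063). As a list, photoreceptor genes had a median of 1.80 in OF (camera adjusted p = 1.2e-22, adjusted p = 0.108 with an estimated correlation) and 1.01 in DR (1.4e-08, adjusted p = 0.406 with an estimated correlation), while cell cycle genes had -0.55 (2.8e-23, adjusted p = 0.108 with an estimated correlation) and -0.25 (2.3e-07, adjusted p = 0.406 with an estimated correlation). In each of these 4 cases at most 1 member passed when adjusted over the list alone. These medians hold the replicate 5 libraries at 48 hpf. The one labelled OF had 2 counts of rho, against 704 to 22972 in the other OF libraries, which may raise the photoreceptor median in OF. Lists of other tissues moved as well. Periocular mesenchyme and neural crest genes fell in OF (median -0.77, camera adjusted p = 1.8e-06, adjusted p = 0.471 with an estimated correlation). They had the lowest p of all lists in DR (median -1.05, camera adjusted p = 8.4e-09, adjusted p = 0.394 with an estimated correlation). The 7 lens genes had a median of 1.72 in OF (camera adjusted p = 7.3e-04, adjusted p = 0.278 with an estimated correlation) and 1.47 in DR (3.9e-04, adjusted p = 0.319 with an estimated correlation, and 0.058 without DR replicate 1 at 56 hpf). No member of these lists passed over all genes or when adjusted over the list alone. Altogether 14 lists were called in OF and 17 in DR, none of them with an estimated correlation. Splits into up and down rest on few calls: 33.3% up in OF (14.3% after quantile scaling) and 50% in DR (25% after quantile scaling, 0% with TMM).

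**Figure D5:**
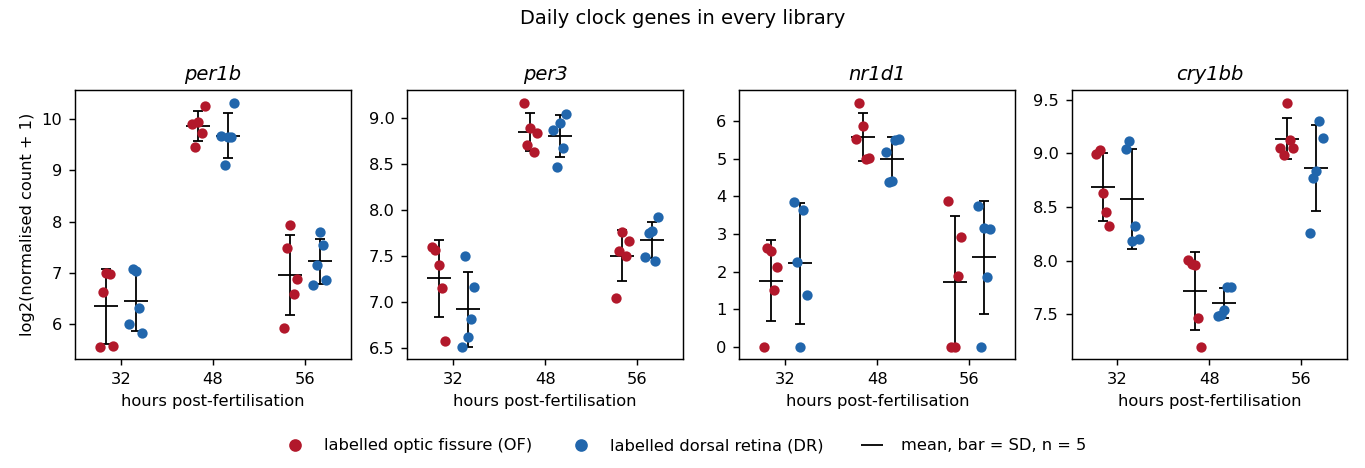
Normalised counts of the clock genes per1b, per3, nr1d1 and cry1bb, as log2(normalised count + 1), against hours post-fertilisation, with 1 point per library in red (OF) or blue (DR), black dashes for means and bars for the SD (n = 5). per1b stood at 946 in OF and 852 in DR at 48 hpf and at 138 and 155 at 56 hpf, and cry1bb moved the other way, while nr1d1 was chosen for display after its values were seen.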

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

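The 3 tests on the replicate 5 pair at 48 hpf, the comparison of photoreceptor genes with other neuron lists and the fits that leave out doubted pairs were chosen after the result was seen. Libraries standing apart were sought in 114 groups of 5 (30 of library measures and 84 of genes), by the gap to the nearest library over the group's range. A library stood apart in 19, where chance gives about 5.7, at 1 in 20. In 4 of these the other 4 libraries were at 0, so that a few reads set the library apart.

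In the replicate 5 pair at 48 hpf, genes of regional identity went against the labels. The library labelled OF stood apart with 18.4 normalised counts of vax1, 21.6 of vax2, 0 of aldh1a3 and 1387 of bambia, and the library labelled DR with 768 of vax1, 565 of aldh1a3, 1.02 of tbx5a and 270 of efnb2a. Across 226 genes that differed at the other times, the difference within this pair had r = -0.64 with the mean fold change at 32 and 56 hpf, against 0.7, 0.76, 0.68 and 0.81 in the other 48 hpf pairs, as an exchange of labels within the pair would give. Low depth is argued against, since the pair held 10.26 M (OF) and 8.06 M (DR) reads in genes, and the other 48 hpf libraries 7.96 M to 12.32 M. The ribosomal protein share and the genes with a read at 4 M reads gave 4 of 4 values inside the range of those libraries. Neither measures degradation directly, so degraded RNA is not excluded. The ventral genes vax1, vax2, pax2a and aldh1a3 argue against a mixture of both regions under the right labels. They are also among the genes that raised doubt about the pair. The library labelled OF held 18, 22, 33 and 0 of them, below all other OF libraries of that time. The library labelled DR held 768, 342, 176 and 565, above all other DR libraries. A mixture would lie between the regions and not turn them around. A smaller admixture stays open. The dorsal gene bambia, at 1387 and 433, lay between the other OF libraries (248 to 356) and the other DR libraries (1633 to 2941) in both. aldh1a2 labelled OF, at 569, lay inside the DR range (223 to 1109). On a scale from DR (0) to OF (1), the library labelled OF lay at 0.21 and the library labelled DR at 0.69. The difference was -0.48, short of the limit set for this test, so the scale could not decide about a mixture. The scale also holds rho, which was low in both libraries. An exchange alone may not be the whole account, because the mean of the photoreceptor list differed by 0.05 within this pair and by 2.22 to 3.16 in the other pairs of that time.

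Other libraries stood apart in single measures. At 32 hpf the replicate 1 libraries had a read in 11777 (DR) and 13854 (OF) genes, where the others of their group had at least 17462 and 17958, and globin shares of 0.21% and 0.551%. At 56 hpf DR replicate 1 had a read in 25740 genes, and DR replicate 2 had 3.22% of reads in mitochondrial genes. vax1 was at 3.8 normalised counts in DR replicate 2 at 32 hpf, and pax2a at 257 in DR replicate 5 of that time. tbx5a was at 0.833 in OF replicate 5 at 32 hpf. saga was at 1.04 in DR replicate 4 and 5.23 in OF replicate 2 at 32 hpf.

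The difference between regions itself changed between 32 and 48 hpf for tbx3a (3.49 on the log2 scale) and, in the paired fit, for 70 genes.

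Photoreceptor genes were higher in OF at 56 hpf, with mean log2 differences of the list of 2.67, 2.23, 3.29, 3 and 3.05 in the 5 pairs. Deeper sequencing of OF is argued against, since the median was 2.53 after thinning each library to 4 M reads and 2.78 before. In 5 of 5 pairs the ganglion cell, amacrine and bipolar lists each had less than 50% of the photoreceptor difference. This does not decide about a general lead of OF in differentiation, because the lists also moved unequally with age. From 48 to 56 hpf within OF the photoreceptor median moved by 1.80 and theirs by 0.24, 0.39 and 0.57. The OF libraries at 48 hpf include replicate 5, with 2 counts of rho against 704 to 22972 in the others. The 1.80 may therefore be too large, and no value without that library is given. A general lead and a local difference in photoreceptor differentiation between ventral and dorsal retina both stay open, and either may instead reflect differences in what was dissected.

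Clock genes as a list turned at 48 hpf, but not each of them. The turn is the smaller of the log2 changes from 48 hpf to 32 and to 56 hpf, and 0 without a peak or trough. It was 0 in both regions for hlfa, hlfb and roraa, among others. The turn of the 34 clock genes other than per1b, per3 and cry1bb had a median of 0.18 in OF and 0.07 in DR. These medians lay at percentiles 100 and 99.3 of 10000 random lists, drawn gene by gene, which does not reflect genes that move together. A difference in the phase of the daily clock between collection times could give this, since 32 and 56 hpf lie 24 h apart and 48 hpf does not share their hour. RNA quality stays open: 5 of 5 calls between 48 and 56 hpf remained with the ribosomal protein share as a covariate, but the share hardly differed between these times (5.33% and 5.16% in OF, 6.69% and 5.86% in DR), so the covariate had little to remove. The hours of collection and the light cycle were not given in the sources used here.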

How the results depend on the processing

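Fits that block pairs within each time or leave out doubted pairs were chosen after the data were seen. Of 138 values of named genes, 105 were called, of which 69 kept their call in all alternatives fixed in advance and 83 in all leave-one-out fits. Of 58 list results 55 were called, and 46 and 44 kept theirs. Among lists the median of endothelial genes in OF from 32 to 48 hpf went from -0.04 to 0.09 with a mean filter of 50, and that of muscle genes at 56 hpf (0.87) ranged from -0.01 to 1.64 without 1 library. No gene reversed. No leave-one-out fit was run with the pairs blocked. The cause of the changes below was not tested, except that a fit to the compared groups alone has fewer samples to estimate the spread and the mean filter tests fewer genes.

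For OF against DR at 32 hpf (198 genes), quantile scaling gave 99, the compared groups alone 39, DESeq2 390, pairs blocked within each time 489, the paired fit 565 and edgeR in that design 451. At 48 hpf (1 gene), a pseudocount of 0.5, no filter, a mean filter of 50 and the compared groups alone each gave 0, TMM, robust variances and edgeR 3 each, the replicate number as a block 4, library weights 116, DESeq2 25 and pairs blocked 35. Leaving out the 48 hpf replicate 5 pair gave 70, both doubted pairs 90, the paired fit 781 and edgeR in that design 839. At 56 hpf (44 genes), a pseudocount of 5 gave 68, the mean filter 26, quantile scaling 86, library weights 259, the compared groups alone 85, edgeR 8, pairs blocked 390, leaving out the 48 hpf pair 73, both pairs 95, the paired fit 820 and edgeR in that design 912. For 1 direction at all 3 times (0 genes with limma), library weights gave 23, DESeq2 4, pairs blocked 1, leaving out the 48 hpf pair 24, both pairs 34, the paired fit 87 and edgeR in that design 107.

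For the interaction at any time (1 gene), quantile scaling and pairs blocked gave 2 each, library weights 5, DESeq2 29, leaving out the 48 hpf pair 7, the 32 hpf pair 4, both 11, the paired fit 63 and edgeR in that design 27. A fit to the compared groups alone was not run there, since all groups are compared. For 48 against 32 hpf (1 gene), library weights gave 3, the compared groups alone 2, edgeR 5, DESeq2 46, pairs blocked 2, leaving out the 48 hpf pair 4, the 32 hpf pair 3, the paired fit 70 and edgeR in that design 26. From 48 to 56 hpf in OF (3 genes), a pseudocount of 5, quantile scaling and library weights gave 7 each, the compared groups alone and edgeR 5 each and DESeq2 10. In DR (2 genes), TMM and the number as a block gave 1 each, and quantile scaling, library weights, DESeq2 and leaving out the 32 hpf pair 4 each. All other counts stayed within 1.5 times, list counts included.

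Leaving out 1 library gave 134 to 292 genes at 32 hpf, 0 to 52 at 48 hpf, 21 to 59 at 56 hpf and 0 to 17 at all 3 times. The interaction gave 1 to 7 at any time, 1 to 4 for 48 against 32 hpf and 0 to 0 for 56 against 48 hpf (limma, 90 at an unadjusted p under 0.05 with all libraries, 0 with edgeR and 0 with DESeq2). Within OF the range was 5049 to 6472 and 3 to 4, and within DR 4038 to 5141 and 1 to 2. Lists called ranged from 11 to 15, 12 to 16 and 10 to 16 at 32, 48 and 56 hpf, from 10 to 16 and 12 to 14 within OF, and from 14 to 15 and 12 to 17 within DR. Quantile scaling shifted the median of all genes by -0.543 in OF and -0.518 in DR from 32 to 48 hpf, by -0.135 for OF against DR at 48 hpf and by -0.116 at 56 hpf, and TMM by -0.129 in OF from 32 to 48 hpf. TMM put the share of rising genes there at 65.3%. Depth limits genes of few reads: 1 read was worth 0.703 to 3.33 normalised counts.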

Other observations

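Fits that block pairs and leave out doubted pairs, and the splits run on them, were chosen after the result was seen. Genes of retinoic acid metabolism split by region at 32 hpf. The synthesis gene aldh1a3, the retinol receptor gene stra6 and cyp26b1, which encodes a retinoic acid degrading enzyme (61.7 ± 35.9 normalised counts in OF and 5.65 ± 4.44 in DR, SD, n = 5; log2 fold change 3.44, SE 0.58, adjusted p = 8.4e-04, and 0.28 with the 32 hpf libraries alone), were higher in OF, while aldh1a2 was lower. Of 18 genes 5 were higher and 3 lower, and 6 and 3 when adjusted over the list alone. The list's call (camera adjusted p = 0.0358, adjusted p = 0.336 with an estimated correlation) ended in 7 of 10 leave-one-out fits, without OF replicate 1, 2, 4 or 5 (0.054, 0.054, 0.058 and 0.052) or DR replicate 1, 2 or 3 (0.1, 0.061 and 0.079), and in the paired fit (0.15).

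Whether other splits of the same libraries give as many calls was counted over 100 splits each, the real one included. Chance could be excluded for genes changed from 32 to 48 hpf, in OF (1 split with as many, 6105 genes, highest other 4507) and in DR (1 split, 4940 genes, highest other 2968). This leaves open a part of the differences in library measures between these times. From 48 to 56 hpf 2 splits had as many in OF (3 genes, highest other 83) and 2 in DR (2 genes, highest other 2). These shares lie under 0.05 but were not adjusted for the number of such tests, and another split matched or passed each count. Chance is therefore not called excluded there. It could not be excluded from splits for OF against DR at 32 hpf (12; 198 genes, highest other 2722), 48 hpf (17; 1 gene, highest other 291) or 56 hpf (7; 44 genes, highest other 373). Several of these other splits call many times the real count, which points to a structure of the samples. At 32 hpf all 11 others left the replicate 1 pair unparted, and likewise the replicate 3 pair. At 56 hpf all 6 others left the replicate 1 pair unparted, and likewise the replicate 2 pair. Whether different pairs shared a side was not counted. For lists called at 32 hpf only the real split had as many (1 split, 13 lists, highest other 12). This share was not adjusted either, and the next split came within a list of it. No splits that part every pair were run for lists, so chance is not called excluded. In DR from 48 to 56 hpf 3 splits had as many (17 lists, highest other 17), and chance is likewise not called excluded. These counts use camera with its preset correlation. With an estimated correlation 5 of the 13 lists at 32 hpf were called and none of the 17 in DR. For the other counts of lists, chance could not be excluded. As many lists were called in 12 splits at 48 hpf (13 lists, highest other 16) and in 22 at 56 hpf (13, highest other 18). In OF 14 splits had as many from 32 to 48 hpf (12 lists, highest other 18) and 18 from 48 to 56 hpf (14, highest other 22). In DR from 32 to 48 hpf 8 splits had as many (15 lists, highest other 16).

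It could also not be excluded for the interaction at any time (25; 1 gene, highest other 110) and between 32 and 48 hpf (21; 1, highest other 164). Counts of 0 with limma, between 48 and 56 hpf (100; highest other 14; 90 genes at an unadjusted p under 0.05, 0 with edgeR and 0 with DESeq2) and at all 3 times (100; highest other 0; 68 unadjusted, 0 with edgeR and 4 with DESeq2), can be met by any split.

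Because the numbers pair OF with DR, splits that part every pair are the closer comparison. There are 16 per time, too few for a share under 0.05, and the real value and highest other were 198 and 4 genes at 32 hpf (1 split with as many), 1 and 56 at 48 hpf (2), and 44 and 0 at 56 hpf (1). The 56 genes came with the 48 hpf replicate 5 pair exchanged. Over 100 drawn splits of this kind the interaction at any time was met by 13 (highest other 61), and the 0 genes at all 3 times by 100 (highest other 2). In the paired fit, 8 splits at 32 hpf (565 genes, highest other 53) and at 48 hpf (781, highest other 0) and 16 at 56 hpf (820, highest other 0) are likewise too few, with 1 split as large in each. The 87 genes at all 3 times were met by 1 of 100 splits (highest other 0) and the 70 interaction genes by 2 of 100 (highest other 502, from a split that exchanged all 4 pairs at 48 hpf, which turns the region difference at that time around). These counts leave chance open, because the 48 hpf pair was left out for regional genes that went against its labels, and vax1 and aldh1a3 are among the 87. With every pair blocked, 1 gene remained at all 3 times and 2 in the interaction.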
